A study of Danio rerio with 2 samples.

How the data were processed

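Poly(A) sites were sequenced from the 3' end of total RNA from 2 pools of zebrafish spleens, 20 unchallenged and 20 bacterially challenged fish, by the SAPAS method, per the labels' protocols. In it, fragmented RNA is reverse transcribed with anchored oligo(dT) primers, amplified by PCR and size selected. Positions are on genome build Zv9, per the submitters' processing notes. The aligner, site caller and filters are not given in the sources used here. Each deposited sample table lists 10032 Ensembl transcripts with the position of every poly(A) site and 1 value per site, and both tables list the same sites. The deposited values are read counts. The file header calls them RPM, but all are whole numbers and sum to 4187557 and 4221286 per library, and the deposited table of shifted transcripts gives the same values for its 848 transcripts under the header Reads. They were used as counts. A second deposited table gives immune genes under headings, with symbols, names and, for part of its 1456 transcripts, reads of both libraries. Of 652 transcripts with reads there, 535 had the values of the sample tables, 25 differed and 92 were not found in the sample tables as used here. Its reads were used where it gave them, and the sample tables otherwise. How the authors made either table is not given in the sources used here. A column headed TTS holds a position that lies upstream of, or at, 99.95% of the sites by a median of 592 nt, and distances were counted from it. The minus strand was reversed so that the proximal site is the one nearest to that position.

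The reference name table matched 0 of the transcript IDs, so gene names come only from the deposited tables, and most transcripts have none (1388 have a name). Reads were summed per symbol for the immune table and per transcript elsewhere. Reads of near-identical copies, such as the C3, MHC and chemokine genes, could be split between them in ways the files do not record.

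Library sizes were the totals of 4187557 (unchallenged) and 4221286 (challenged) reads, multiplied by TMM factors (0.799 and 1.25), computed from the published formula in Python with trims of 30% on log ratios and 5% on abundance. The design had named the packaged version of TMM, and the formula was used because a cell of the tables holds a list of counts. With 1 library per group no test was made. A rule of size, fixed before the data were examined, called a gene higher or lower when the ratio was at least 2-fold and its 95% counting interval (Clopper-Pearson on the share of the 2 counts) excluded 1, with at least 20 reads summed. A fold against 0 reads is given as a bound against a floor of 3 counts, which leaves out the error of the other count, so the limit of the counting interval stands beside it. PCR reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only.

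For poly(A) sites, transcripts with 2 or more sites and at least 20 reads in each library were called when the share of reads at the proximal site differed by at least 10 percentage points and the 95% Newcombe interval excluded 0. Shares have exact binomial intervals. To see what counting error gives, both libraries were drawn 100 times from the pooled site shares at the real depths.

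Before the data were examined, 24 lists of pathways and cell type markers were fixed and matched by symbol, ignoring case. Over them 87 distinct members could be tested, of which 39 were higher, 19 lower and 29 neither. A list with at least 3 tested members got the percentile of its median log2 ratio among 10000 random lists matched on abundance in 20 bins. Counts of 0 were set to 3 for medians. After the data were seen, 118 transcripts were matched to the lists by full name, and the study's immune headings were joined into 20 groups. Overlaps of tables were set against random lists matched the same way.

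Named genes followed a rule fixed beforehand. It took the 8 highest and 8 lowest log2 ratios among immune-table symbols with at least 200 reads, leaving out clone-type symbols, and up to 3 members at each end of every list (the 2 most abundant, as values, where none passed). For poly(A) it took the 6 largest shifts each way with at least 100 reads in each library and up to 6 in both deposited tables. Symbols exist only in the immune table, so for poly(A) the rule was applied to transcripts with a descriptive name. Other named genes were chosen after their values were seen, namely fibrinogen alpha, C7 (2 of 2), a complement factor B transcript, ptprc, the second tapbp transcript and those in the closing section.

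Both rules were tested on simulated counts with 200 changed transcripts, drawn from the pooled means and the real library sizes for the comparison of the 2 libraries. Of 6873 transcripts tested there, the expression rule called 98.9% of those changed 3-fold and 100% of those changed 8-fold, and 0.717% of unchanged ones. On 2208 transcripts the poly(A) rule called 84% of shifts of 20 percentage points, 100% of shifts of 40, and 1.05% of unchanged ones. The simulation holds counting error and no variation between fish or amplifications.

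Alternatives covered the scaling (total reads, and the median of ratios over genes), the read minimums, the size of fold and shift, a pseudocount of 1 normalized unit, minor sites under 5%, thinning of the deeper library and the background of overlaps. Added after the data were seen were totals without the 20 most abundant transcripts, matching by name, counts of the sample tables only, a length rule of 50 nt, and poly(A) counts without transcripts that were lower. Python 3.11.15 was used with NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9.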

Results

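Poly(A) sites and the reads at each of them were measured in the spleen of adult male wild-type zebrafish (6 months old) by sequencing the 3' ends of transcripts. There were 2 libraries, each from the pooled spleens of 20 fish. The first pool came from unchallenged fish and the second from fish taken 15 hours after an intraperitoneal injection of Staphylococcus aureus, a Gram-positive bacterium. With 1 library per group there is no replicate check and no p-value. Every ratio below compares these 2 libraries, and its 95% interval covers counting error only. The unchallenged library held 4187557 reads and the challenged library 4221286 reads over the same 10032 transcripts and 16653 poly(A) sites of genome build Zv9. Of these transcripts 3914 had 2 or more sites. Reads were found for 7811 transcripts in the unchallenged and 8576 in the challenged library. The polyadenylation signal AATAAA was listed for 55.0% of the sites and ATTAAA for 18.0%.

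The first comparison asked which transcripts differed in abundance between the challenged and the unchallenged spleen pool. Only 1388 transcripts have a name in the tables, and genes were ranked among the symbols of the deposited immune table, so the genes named at either end are immune genes by that choice. The highest in the challenged library included the antiviral GTPase MxC, the chemokine CCL19, the neutrophil oxidase subunit p47phox and the inflammatory cytokine IL1b. Complement components (C5, C8 and the C3 copy listed as 5 of 6) and the clotting factor prothrombin were among the lowest of that table. The more abundant C3a, C3b and C3c were 3.71-fold, 2.51-fold and 3.89-fold lower. Among 6919 transcripts with at least 20 reads summed, 2365 were at least 2-fold higher and 2025 at least 2-fold lower in the challenged library with a counting interval that excluded a ratio of 1, and 2529 met neither condition. Transcripts in the lower set held 51.3% of the unchallenged and 9.39% of the challenged reads.

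These ratios rest on trimmed mean of M values (TMM) scaling, under which 53.9% of the called transcripts were higher. Scaling by total reads gave 3132 higher and 1502 lower, or 67.6% higher, and moved the median log2 ratio from 0.12 to 0.76, a shift of 0.65 that applies to every ratio. The share called was smaller at greater depth, from 74.6% of transcripts with 20 to 99 reads summed to 43.6% of those with 10000 or more. The Spearman rank correlation between the reads of the 2 libraries over the tested transcripts was 0.515. Noise beyond counting error was not set apart from these calls.

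The deposited immune gene table pairs transcripts with symbols. Of its genes 511 had at least 20 reads summed, of which 220 were higher, 130 lower and 161 neither. Under total scaling 271 were higher and 102 lower. The study chose this table, so its directions are not independent evidence. MxC (ENSDART00000012694), which blocks virus replication, had 3 reads in the unchallenged and 815 in the challenged library, a ratio of 172 (58.7 to 836). CCL19 (ENSDART00000099611), which attracts lymphocytes and dendritic cells, had 180 and 42356 reads, 149-fold higher (129 to 174). The chemokine CCL-C24c had 0 and 425 reads, at least 89.7-fold higher against a floor of 3 counts, with a lower limit of the counting interval of 72.7. On the same floor IL1b was at least 54.9-fold higher (lower limit 44.3), the adhesion receptor CD44 at least 47.3-fold (38.1) and the acute-phase protein SAA1 at least 42.2-fold (34.02). The oxidase subunit p47phox was 68.1-fold higher (26.4 to 251) and the pro-apoptotic gene BAXa 49.3-fold higher (22.5 to 135). At the other end, the entry with the symbol ITGB1 (ENSDART00000037808, named integrin, beta 1b.2) had 396 reads in the unchallenged library and 0 in the challenged library. It was at least 208-fold lower on that floor, with an upper limit of 0.00593 for the ratio. The kinase gene AKT2L was 23.3-fold lower (20.3 to 26.8), C3 (5 of 6) 21.3-fold (17.1 to 26.9), C8 20.2-fold (15.6 to 26.6), the lectin-pathway protease MASP-3 19.5-fold (12.6 to 31.7), the actin regulator VASP 17.6-fold (11.6 to 28.0), C5 15.6-fold (10.5 to 24.1) and prothrombin 15.4-fold (14.0 to 16.9).

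**Figure D1:**
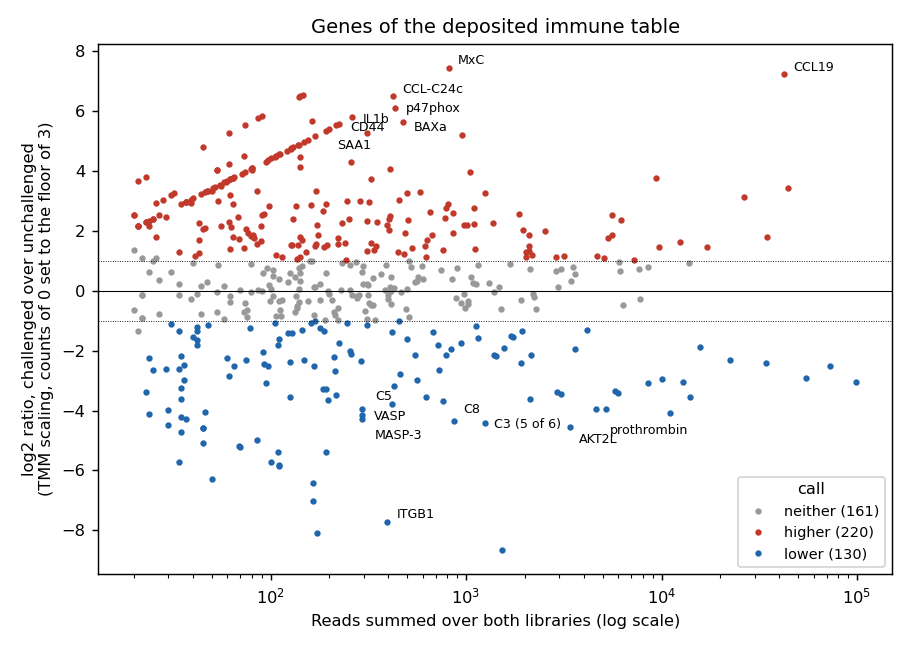
Each point is a gene of the deposited immune table, plotted by its reads summed over both libraries (log scale) and its log2 ratio of challenged over unchallenged, with counts of 0 set to the floor of 3. Red points (220) were higher and blue points (130) lower by the rule of size, grey points (161) neither, dotted lines mark 2-fold, and labels name the 8 genes at either end among those with a symbol and at least 200 reads.

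Of the fixed list of cytokines and chemokines 6 of 10 tested members were higher in the challenged library and 1 was lower, and the median log2 ratio of 2.82 lay at percentile 99.8 of 10000 random lists matched on abundance. With no read minimum the median was 1.46. Besides IL1b, the anti-inflammatory cytokine IL10 had 1 and 60 reads (ratio 38.001, 6.56 to 1526) and the chemokine CXCL-C1c 3 and 153 reads (ratio 32.3, 10.8 to 158). TNFSF13b, a B cell survival factor, was 2.03-fold lower (1.48 to 2.79), a call that total scaling ended. The larger group of chemokines and chemokine receptors from the study's headings, joined after the data were seen, had 13 of 28 tested genes higher, 6 lower and a median of 0.77 inside the random range (percentile 83.6). Toll-like receptor and NF-kB signalling had 6 higher and 2 lower among 15 tested members, with a median of 0.83 inside the range of random lists (percentile 86.2), as was its median when matched by name (13 of 27 higher, 4 lower, percentile 97.0). The inhibitory kinase-like gene IRAK3 was at least 31.5-fold higher (lower limit 25.3), the adaptor TRAF3 at least 7.81-fold (6.04) and the adaptor MyD88 7.92-fold (2.91 to 30.2). The receptor TLR4ba, with 163 and 2 reads, was 129-fold lower (35.06 to 1072, log2 ratio -7.01, or -5.17 with a pseudocount of 1) and the kinase MAP3k7 3.38-fold lower (2.95 to 3.90).

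Interferon-stimulated genes were higher as a group, with 10 of 15 tested members higher, 1 lower and a median log2 ratio of 2.199 (percentile 99.6). MxA was 26.2-fold higher (8.75 to 129) and the transcription factor STAT1b 21.9-fold higher (8.34 to 81.3). STAT2 was 2.54-fold lower (1.88 to 3.46) and lost that call under total scaling. The JAK-STAT and feedback list, which shares STAT1a, STAT1b and STAT2, had 10 higher and 1 lower of 15, with a median of 1.56 inside the random range (percentile 95.9). Its feedback inhibitors SOCS1a and SOCS3b were 9.92-fold (3.19 to 49.8) and 6.80-fold (5.50 to 8.49) higher. In the study's own headings, grouped after the data were seen, interferon-induced GTPases had 8 of 9 tested members higher and a median of 3.71 (percentile 99.97). All groups of headings were chosen by the study and give no independent evidence of direction.

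Both tested neutrophil markers were higher. Lysozyme (LYZ), an antibacterial enzyme of granules, had 2495 and 42102 reads, 10.7-fold higher (10.3 to 11.13), and myeloperoxidase (MPX) was 3.42-fold higher (1.72 to 7.53). With members matched also by full gene name, a step added after the data were seen, all 5 tested neutrophil members were higher with a median log2 ratio of 3.42 (percentile 99.6). The acute-phase and antimicrobial list matched by symbol held LYZ, MPX and C-reactive protein (CRP), the last 5.75-fold lower (3.14 to 11.3). Its median of 1.77 lay inside the random range (percentile 86.5), while matched by name it had 7 of 11 higher and 3 lower and a median of 1.80 outside its own random range (percentile 98.3). With the counts of the sample tables only, the median of the list matched by symbol was 0.45. The stress and immediate early list had 3 higher and 1 lower of 5, with Egr1 4.89-fold (2.22 to 12.7), ATF4b1 4.08-fold (3.06 to 5.54) and ATF4b2 3.54-fold (1.897 to 7.18) higher and the chaperone gene HSP70 3.36-fold lower (2.52 to 4.50), and its median of 1.82 was at percentile 92.0, or 0.59 with a minimum of 100 reads. Matched by name it had 4 of 12 higher and 2 lower with a median of 0.57 (percentile 90.1).

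Most complement genes were lower in the challenged library. On the fixed list 11 of 13 tested members were lower and 1 was higher, with a median log2 ratio of -2.78 (percentile 0.19), or -1.96 with no read minimum or the sample tables only. Matched by name 19 of 29 were lower and 3 higher, with a median of -1.90 (percentile 0.01). C5 and C6 of the terminal pathway were 15.6-fold and 12.2-fold lower (4.33 to 47.7 for C6), the factor H-like gene CFHL4 was at least 19.5-fold lower (upper limit of the ratio 0.0664), and C7a was 4.35-fold higher (2.06 to 10.6). C7 (2 of 2), with 416 and 8937 reads, was 13.6-fold higher (12.3 to 15.05), and 1 complement factor B transcript 15.6-fold higher (11.4 to 21.8). Summed over the transcripts matched by name, however, factor B had 1631 and 1573 reads, a ratio of 0.61 (0.570 to 0.655) that was called neither. The wider group of complement proteases, components and regulators from the study's headings had 30 of 38 tested members lower and 5 higher, with a median of -2.55 (percentile 0). Complement recognition proteins did not follow, with 2 of 6 lower and 4 neither. Their median of -0.53 lay inside the random range (percentile 19.3) and flipped to 0.12 under total scaling. Of complement receptors, found on leukocytes, 7 of 11 were higher and 0 lower, with a median of 1.46 inside the random range (percentile 96.8). Liver plasma-protein transcripts were lower together with complement. Matched by name, 10 of 11 tested liver members were lower and 1 was higher, with a median of -3.06 (percentile 0.5). Fibrinogen alpha had 83470 reads in the unchallenged and 15784 in the challenged library, 8.35-fold lower (8.21 to 8.49), while the haem-binding protein HPX, the only member matched by symbol, was 2.22-fold higher (2.04 to 2.42).

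**Figure D2:**
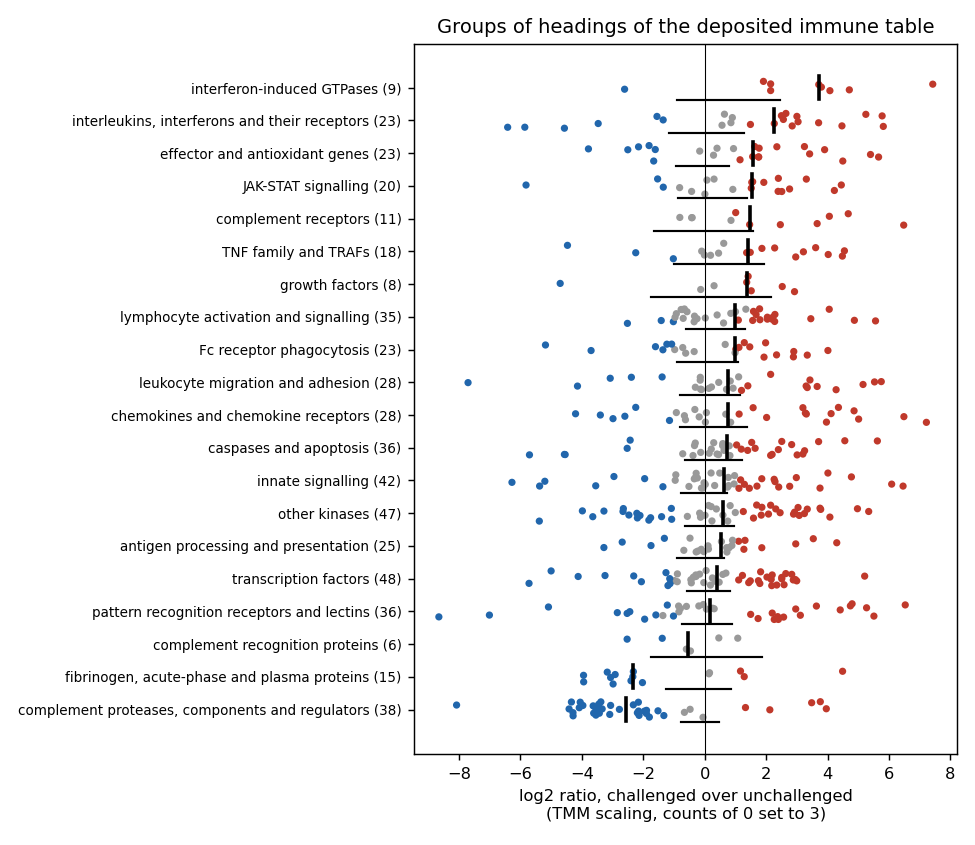
Points are genes of 20 groups of the study's immune headings (tested genes in parentheses), placed by log2 ratio of challenged over unchallenged and coloured red for higher, blue for lower and grey for neither. Thick ticks are group medians and thin bars the central 95% of medians of random lists, and the complement protease group (median -2.55) and the fibrinogen and plasma protein group (median -2.34) lie to the left of their bars.

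Markers of other cell types were few in the tables, and 6 of the 24 fixed lists had no member matched by symbol. Among macrophage markers 1 of 4 tested members was higher, the transcription factor IRF8 at 4.59-fold (3.39 to 6.35), and the list median of 0.53 was at percentile 53.7 (-0.04 when matched by name, which flipped to 0.60 under total scaling). Of 3 T and NK cell markers the gut-homing receptor CCR9a was 6.05-fold lower (2.40 to 18.2), and the median was -0.92 (percentile 5.09). That sign did not hold, since the median was 0 with no read minimum and 0.20 (percentile 19.7) when matched by name, which adds the leukocyte gene ptprc at 2.51-fold higher (1.8997 to 3.37). Among 3 endothelial and stromal markers the VEGF receptor KDRL was 2.86-fold higher (1.84 to 4.61), with a median of 0.06 (percentile 57.4) that was -0.04 with no read minimum. The erythroid transcription factor GATA1a was 4.17-fold lower (2.59 to 6.90). On the glycolysis list the growth factor VEGFaa, which is not a glycolytic enzyme, had 3 and 36 reads, a ratio of 7.60 (2.40 to 38.6). Of antigen presentation, the chaperone CANX had a ratio of 1.88 (1.80 to 1.95) and TAPBP a ratio of 0.72 (0.576 to 0.897), whose direction flipped under total scaling, and neither passed the rule, though CANX did under total scaling (log2 ratio 1.55). A second transcript matched by name to tapbp had 8 and 286 reads, 22.6-fold higher (11.3 to 53.0). The B cell members BLNK (0 and 19 reads) and Syk (0 and 15 reads) were below the minimum. The match to the ribosomal list was RPS6KB1, a kinase and no ribosomal protein, with a ratio of 0.65 (0.544 to 0.781) that flipped to a log2 ratio of 0.03 under total scaling.

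The second comparison asked whether transcripts used different poly(A) sites in the challenged pool. More shifts were called than counting error alone gives, to either side in near-equal number and mainly at low depth. Of 2208 transcripts with 2 or more sites and at least 20 reads in each library, 322 shifted to the proximal site (shorter 3' untranslated region, UTR) and 347 to more distal sites (longer 3' UTR) by at least 10 percentage points with an interval that excluded 0, and 1539 did neither. Counting error alone gave a median of 27 such calls, and at most 43, in 100 simulated draws. The median shift was 0 percentage points and the median absolute shift 3.45. At 92 transcripts the proximal site had 0 reads in 1 library and 50 or more in the other.

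**Figure D3:**
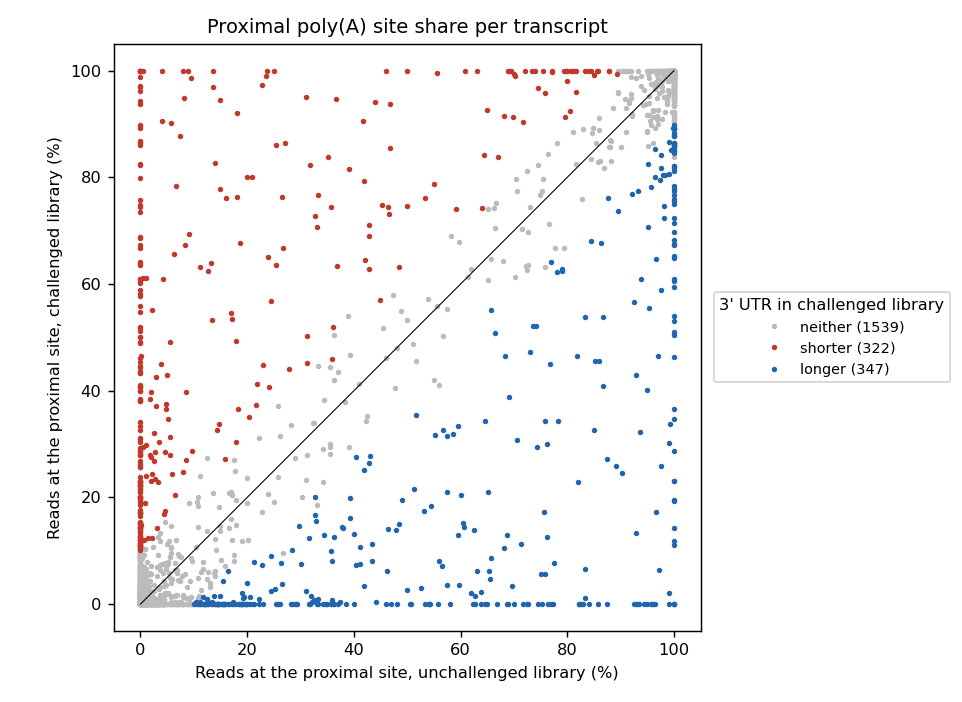
Each point is a transcript, placed by the percent of its reads at the proximal poly(A) site in the unchallenged (horizontal) and the challenged library (vertical), with the line of equal share. Red points (322) have shorter and blue points (347) longer 3' UTRs in the challenged library, grey points (1539) neither, and many coloured points lie on the frame at 0 or 100%.

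TSC22 domain family 2, a transcriptional regulator gene, had the largest shift to a shorter 3' UTR among named transcripts with at least 100 reads in each library. The site on chromosome 22 at 38148471 took 4.09% of its 342 reads (95% exact interval 2.26 to 6.77) in the unchallenged and 90.6% of its 117 reads (83.8 to 95.2) in the challenged library, against the distal site at 38148906. RNA binding protein S1, of the splicing machinery, went from 0 of 112 reads to 61% of 100 reads (50.7 to 70.6), and the motor subunit dynein cytoplasmic 1 intermediate chain 2 from 0 of 153 to 60.9% of 202 (53.8 to 67.7). The co-chaperone DnaJ (Hsp40) B9 shifted by 60.8 percentage points (53.0 to 67.9), transmembrane protein 131 by 60.2 (50.8 to 68.4) and glycogenin 1, which primes glycogen synthesis, by 59.3 (53.2 to 64.6). Toward longer 3' UTRs, chromosome 8 open reading frame 55 used its proximal site, on chromosome 2 at 52319272, for 96.5% of 202 reads (93.0 to 98.6) in the unchallenged library and for 0 of 161 in the challenged library, an exact upper bound of 2.27%. GDP-mannose pyrophosphorylase Ab went from 94.9% to 0, the cargo receptor cornichon homolog from 94.4% to 0, the ubiquitin ligase subunit F-box and WD repeat domain containing 7 from 82.6% to 0, CD99 antigen-like 2 from 76.9% to 0 and transmembrane protein 115 from 83.3% to 6.67%. These 6 had 130 to 327 reads in the unchallenged and 150 to 282 in the challenged library. No polyadenylation signal was listed for the proximal site of F-box and WD repeat domain containing 7 (270 and 0 reads). The other transcripts named in this paragraph had a signal, AATAAA or a variant, listed at theirs.

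Immune genes that the study lists as shifted included BAXb, MHC class II beta, ENDO-G, TAB2 and Ikaros. The proximal share of the apoptosis gene BAXb was 0 of 32 reads in the unchallenged and 97.1% of 104 reads (91.8 to 99.4) in the challenged library. MHC class II beta went from 0 of 88 to 89.3% of 56 reads (78.1 to 96.0), the mitochondrial nuclease ENDO-G from 0 of 28 to 73.5% of 34 (55.6 to 87.1) and the signalling adaptor TAB2 from 0 of 88 to 58.2% of 141 (49.6 to 66.4). The lymphoid transcription factor Ikaros went the other way, from 50.6% of 81 reads (39.3 to 61.9) to 0 of 48. No polyadenylation signal was listed for the proximal sites of BAXb (0 and 101 reads) and TAB2 (0 and 82 reads). AATAAA was listed for those of MHC class II beta and ENDO-G, and AATGAA for that of Ikaros. Whether sites without a signal are true transcript ends was not tested.

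The poly(A) shifts were found mainly at low depth. Of transcripts with 20 to 99 reads in the library with fewer, 40.9% (37.95 to 43.9) were called, against 2.96% (0.967 to 6.77) of the 169 with 1000 or more.

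**Figure D4:**
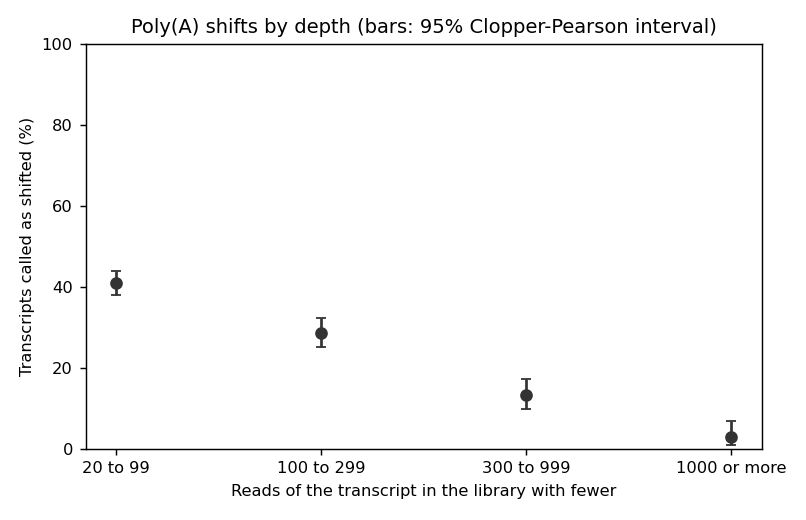
The percent of transcripts called as shifted is plotted against the reads of the transcript in the library with fewer, with 95% Clopper-Pearson intervals. The circles go down from 40.9% to 2.96%.

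The deposited table of shifted transcripts lists 848, of which 407 stand under Shorten and 441 under Lengthen, with a test and threshold that are not given in the sources used here. Of the 645 with at least 20 reads in each library, the rule of size called 204 of 314 Shorten transcripts shorter and 2 longer, and 210 of 331 Lengthen transcripts longer and 1 shorter. Another 252 transcripts that it called were not in the table. The table comes from these same libraries and is not independent evidence of direction. Immune genes did not stand out in it. Among evaluable transcripts 41 were in both deposited tables, where expression-matched random lists gave a median of 43 (32 to 53). Immune-table transcripts were found among those higher in the challenged library more often than random lists (192 against a median of 146, 128 to 164) and among those lower less often (106 against 128, 110 to 146).

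The third comparison set the poly(A) shift of each transcript against its expression ratio. Transcripts with longer 3' UTRs in the challenged library had a median log2 expression ratio of -0.32, at percentile 0.81 of matched random lists. Those with shorter 3' UTRs had -0.04 (percentile 76.8) and unshifted ones -0.05 (percentile 90.7). Total scaling adds the same 0.65 to each, giving 0.33, 0.61 and 0.59, and leaves the gaps between the sets as they were. Across the 2208 transcripts Spearman's rho between the shift of the proximal share and the log2 ratio was 0.083. Transcripts are not independent replicates.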

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

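Chosen after the data were seen were the alternatives that match lists by full name, use the sample tables only, leave out the 20 most abundant transcripts or the transcripts that were lower, or use the weighted 3' UTR length. No paired analysis was possible because each group is 1 library, so no library could be left out and no other split of the samples made. Total scaling moved the median log2 ratio from 0.12 to 0.76, since it sets the factors of 0.799 and 1.25 to 1, and kept 3867 of the 4390 calls. The median of ratios kept 4386. A minimum of 100 reads summed tests fewer transcripts and gave 1270 higher, 1160 lower and 23 list members higher. Matching by name adds members and gave 75 higher and 47 lower, against 39 and 19. For shorter and longer 3' UTRs, a minimum of 50 reads in each library gave 197 and 203, a minimum of 100 gave 110 and 120 with 1135 transcripts left, any shift gave 551 and 558, and a shift of 20 percentage points gave 224 longer. With all listed transcripts as the background, 241 transcripts of the deposited poly(A) table were higher (137 among evaluable ones), 114 of them in Shorten (66) and 127 in Lengthen (71), as more transcripts enter. The remaining counts stayed within 1.5 times, and Spearman's rho stayed between 0.066 and 0.088. None of the 50 genes named by the fixed rule changed direction under the scalings or the pseudocount if it was called (genes named after their values were seen were not part of this). That outcome was fixed in advance and says nothing of stability. A call needs a ratio of at least 2-fold, total scaling adds only 0.65 to a log2 ratio, and a pseudocount on both values keeps its sign. Thinning says nothing of stability either, since the library totals are nearly equal. Medians of lists did change sign: under total scaling the complement recognition headings (-0.53 to 0.12) and, matched by name, the macrophage (-0.04 to 0.60) and cleavage and polyadenylation lists (-0.19 to 0.46). The median of Toll-like receptor and NF-kB members (0.83) was 0.40 with 100 reads, 1.48 under total scaling and 1.59 with the sample tables only. Of these 50 genes, 22 left their counting interval under total scaling and 2 with the pseudocount. The pseudocount moved 15 by more than 1.5-fold, all with 6 or fewer reads in a library, among them the log2 ratios of MxC (7.43 to 6.36), IL10 (5.25 to 3.25), CXCL-C1c (5.01 to 3.98), MxA (4.71 to 3.69) and C6 (-3.61 to -2.55). Leaving out erythroid genes removed 1 transcript, since no haemoglobin name was found in the tables used here, and says nothing of stability. Of the 2208 transcripts evaluated for poly(A) shifts 1073 had under 100 reads in a library.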

Other observations

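The tests of scaling and of a common factor on liver transcripts, the tests of dilution and of a neutrophil share on immune-table genes, the lists matched by name and the groups of headings were chosen after the results were seen.

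Of the 4 glycolysis list members matched by name 3 were higher and 1 lower (median log2 ratio 2.93, percentile 99.7), but 1 of those higher is VEGFaa, which is no enzyme. Hexokinase 2 (hk2), the first enzyme of glycolysis, had 17 and 2001 reads, 74.5-fold higher (95% counting interval 46.4 to 128), and lactate dehydrogenase ldha was 7.62-fold higher (6.10 to 9.64), while the enzyme pgam1a was 3.81-fold lower (3.47 to 4.19). All 3 tested thrombocyte markers were higher (percentile 88.1, inside the random range), with itgb3b at 4.81-fold (3.07 to 7.88) and itga2b at 2.07-fold (1.54 to 2.81). Of 3 erythroid markers 2 were lower (percentile 7.995, inside the range), rhd 10.3-fold (7.14 to 15.4) and GATA1a 4.17-fold (2.59 to 6.90). Of 11 antigen presentation members 4 were higher and 0 lower (percentile 96.8, inside the range, and 7 higher under total scaling), among them the second tapbp transcript at 22.6-fold (11.3 to 53.0) and the proteasome activator genes psme1 at 3.63-fold (3.37 to 3.91) and psme2 at 2.49-fold (2.23 to 2.77). TAPBP matched by symbol counted as a separate member, with a ratio of 0.72 that was called neither. Its reads were not summed with those of the second transcript. The 4 named members of the cleavage and polyadenylation machinery had a median log2 ratio of -0.19 (percentile 46.4), which flipped to 0.46 under total scaling, and only hnrnph1l was called, 9.50-fold higher (5.73 to 16.9).

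Caspase and apoptosis headings had 16 of 36 tested genes higher and 5 lower (median log2 ratio 0.72, percentile 84.6), TNF family and TRAF headings 10 of 18 higher and 3 lower (1.43, percentile 91.2), and lymphocyte activation headings 16 of 35 higher and 3 lower (1.004, percentile 92.7). These genes were picked by the study. Some of the most abundant transcripts carry no name in the tables, among them 4 picked here for their size. ENSDART00000135084 on chromosome 16 took 12.8% of unchallenged and 0.853% of challenged reads, 23.6-fold lower, and ENSDART00000028565 on chromosome 22 was 26.7-fold lower. ENSDART00000051972 on chromosome 19 was 9.45-fold higher with 4.32% of challenged reads, and ENSDART00000123667 on chromosome 18 was 7.63-fold higher. In the immune table, a gene without a symbol that is named as similar to serum amyloid P-component had 1530 and 6 reads, 403-fold lower (185 to 1099).

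Poly(A) site usage differed between the 2 libraries by the rule at 30.3% of evaluable transcripts, far more than counting error gave. Noise of amplification or sampling beyond counting error predicted that few deep transcripts are called, and 2.96% of those with 1000 or more reads in each library were, against 40.9% at 20 to 99 reads, so such noise fits and the calls at low depth may rest on it. Deep transcripts may instead have 1 dominant site and no room for a shift, which stays open: among those with a pooled proximal share of 20 to 80% the share called was 86.8%, 78.9%, 52.6% and, in 10 deep transcripts, 40% (12.2 to 73.8), but a shift itself brings a transcript into that range, so the split decides nothing. A changing mixture with RNA of another tissue stays open too, since at 100 or more reads the share called was 1.95 percentage points higher (-4.48 to 8.68) among transcripts that were lower than among unchanged ones, and an effect of the challenge was not tested apart from these.

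Liver plasma-protein transcripts were lower in the challenged library. The choice among 4 scalings cannot account for this, since the median log2 ratio of the liver list was -3.06 and at most -2.41 over them. That outcome was fixed once the median was seen, because total scaling adds only 0.65 to each log2 ratio. It is therefore no separate test of abundant transcripts changing the scaling. A smaller carried-over share of liver RNA as the whole cause predicts 1 common factor, and 2 of 10 members with 100 or more reads had an interval wholly more than 2-fold from the list median, HPX (2.22-fold higher) and kng1 (191-fold lower, 139 to 268). It may be part of the source, but the other 8 members, within that tolerance, ranged in ratio from 0.0586 (itih2, 0.0474 to 0.0718) to 0.2001 (cp, 0.194 to 0.206), further apart than counting error, so the test does not show a single factor. Of the 12 liver members 2 are on another list and all come from the study's tables, and lower expression of these genes in the fish after challenge was not tested.

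Of the immune-table genes 220 were higher and 130 lower in the challenged library (271 and 102 under total scaling). Most tested complement members were lower, and most tested members of the cytokine and interferon-stimulated lists were higher. For those that were higher, dilution in the unchallenged library by its abundant transcripts could raise every other ratio by at most 2.05-fold. Of all 511 tested immune genes 46.97% (42.6 to 51.4) had an interval under total scaling wholly above that. Counting error gives at most 2.5%, so dilution with counting error alone is not the whole cause. These intervals hold no amplification noise, so dilution together with such noise was not excluded. Whether that share sets immune genes apart was not tested, since it was not computed for all transcripts. By the looser rule of size, total scaling called 271 of the 511 immune genes and 3132 of all 6919 tested transcripts higher. A larger share of neutrophils at fixed expression per cell as the whole cause cannot be told apart from higher expression per cell, since 2 of 5 neutrophil members lay wholly more than 2-fold from the list median, between the bounds set for either reading. The challenge itself stays open as the source, untested with 1 library per group.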
